A study of Homo sapiens with 12 samples.

How the data were processed

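RNA was measured by sequencing in 12 libraries of LNCaP, an established human prostate cancer cell line. The labels assign 2 libraries to each of 6 groups, which are an empty vector line (EV) and lines transduced with retroviruses to express stably FOSL1, YAP, TAZ, YAP with FOSL1, or TAZ with FOSL1. YAP is encoded by YAP1 and TAZ by WWTR1. Per the labels' protocols, cells were grown in RPMI medium with fetal bovine serum, RNA was extracted with TRIzol, and libraries were made with a stranded kit for polyadenylated RNA. The labels give no batch or date. They do not say whether replicates came from separate cultures, so every p-value measures the spread between these libraries, which may be technical.

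The deposited values are raw read counts per gene, 1 column per library, per the file headers, which have the layout that featureCounts writes. Per the submitters' processing notes, Trim Galore, STAR 2.6 and featureCounts of the Subread package were used with the genome build hg19 (GRCh37.p13). The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Values of gene families with near-identical copies, of overlapping genes and of antisense genes are therefore uncertain. Reads from a transgene and from the cell's own copy of the same gene cannot be told apart in gene counts. Coordinates are those of the deposited table, in hg19. Of the table's 57820 gene identifiers, 39538 were paired with a symbol through a table of gene names. Depth was between 24914014 and 29668689 counts per library, so that 3 counts, taken as the floor, correspond to between 0.101 and 0.12 CPM (counts scaled by library size). No pair of replicates agreed within sampling noise. The chi-square statistic per degree of freedom between replicates was 2.01 in FOSL1, 2.47 in EV, 2.60 in TAZ with FOSL1, 6.93 in TAZ, 8.91 in YAP and 10.8 in YAP with FOSL1, so each library counted as 1 replicate.

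Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which kept 19351 genes, 16938 of them with a symbol. Library sizes were scaled by TMM factors between 0.974 and 1.018. The quasi-likelihood test of edgeR, with robust estimation and all 12 libraries in 1 fit, was applied to 13 comparisons: each line against EV, each double line against both of its single lines, YAP against TAZ, the double lines against each other, and the interactions of YAP and of TAZ with FOSL1. An interaction is the log2 fold change of the double line against its YAP or TAZ line minus that of FOSL1 against EV. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, genes with an adjusted p under 0.05 are called changed, and the tests are two-sided. The biological coefficient of variation was 0.0585. All lines share 1 estimate of the spread per gene, although replicate noise differed between lines. The p-values may therefore be too small among YAP, TAZ and YAP with FOSL1, and too large among the lines with quieter replicates. Values after ± are standard errors of log2 fold changes unless marked SD, and n is 2 libraries per group throughout. These errors are the absolute log2 fold change divided by the square root of the test's F statistic. For large changes from few counts they may be too small.

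The 20 gene lists and the comparisons were chosen before the data were examined. Of these, 1 list is not reported here, and the others were YAP/TAZ targets, Hippo pathway and TEAD factors, other AP-1 members, invasion genes linked to AP-1, luminal prostate, basal epithelial, stem cell and neuroendocrine markers, mesenchymal transition genes, actin cytoskeleton and focal adhesion genes, cell cycle genes, interferon-stimulated genes, NF-kappaB inflammatory genes, cholesterol synthesis genes, genes of the unfolded protein and amino acid stress response, hypoxia and glycolysis genes, fibroblast and immune cell markers, and heat shock and handling stress genes. Each list was set against the other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. Counts of changed members are given over all genes tested and, where it differs, adjusted over the list alone. List medians include fitted values of genes with 0 counts in a group. Setting those genes to their fold against 3 counts over the group moved 3 of 220 medians by over 0.1, and the value so obtained is given beside those that are printed. The same step moved 0 of 40 interaction medians by over 0.1, by 0.05 at most.

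Named genes were chosen by a fixed rule. It took FOSL1, YAP1 and WWTR1 everywhere, the 8 largest and 8 smallest changes against EV (5 and 5 in other comparisons) among called genes with an average log2 CPM of at least 1 and separated libraries, up to 4 members per list with the smallest p, and a fixed set of KLK3, TMPRSS2, CCN2, CCN1, ANKRD1, AXL, CD44, KRT5, KRT8, CHGA and SYP, with 2 further genes that are not reported here. Genes with clone-based names and pseudogenes were left out of the largest and smallest changes. AXL, KRT5 and CHGA fell below the expression filter and were not tested.

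Correlations of responses that share the EV libraries are given beside those of simulated data with no change in any line. In each of 50 simulations all 12 libraries, EV included, were drawn from the mean level of EV. The spread per gene was that estimated over all lines. Slopes of the FOSL1 response were also taken from 1 library of each line, over each choice of libraries, and interactions were called again without 1 FOSL1 and 1 EV library to compare their sign with the response of that pair. These checks were chosen after the data were seen. The method was tested on simulated counts with known changes. Changes of log2 0.5, 1 and 2 were given to 67, 67 and 66 genes, all above 1 CPM in EV. The spread per gene was equal in all lines, unlike the replicate noise seen here. The shares below may therefore not carry over to the real comparisons. For FOSL1 against EV, with 18421 genes, 70.1% of genes changed by log2 0.5, 91.0% of those changed by log2 1 and 98.5% of those changed by log2 2 were called, and 6.99% of calls were unchanged genes. For the interaction of YAP with FOSL1, with 18425 genes, these shares were 40.3%, 85.1% and 90.9%, with 9.43% of calls on unchanged genes. Alternatives were size factors as DESeq2 computes them, upper-quartile factors, no filter on low counts, DESeq2 1.42.0, only the groups compared in the fit, the replicate number as a block, a threshold of 0.01, and leaving out each library in turn, in which case the lone library is assumed to vary like the other groups. A test against a fold of 1.5 and a fit without mitochondrial genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, proteins and phenotypes were not analysed here.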

Results

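RNA abundance per gene was measured by sequencing of polyadenylated RNA in LNCaP cells, a human prostate cancer line. The cells stably carried an empty vector (EV) or expressed FOSL1, YAP, TAZ, YAP with FOSL1 (YAP/FOSL1) or TAZ with FOSL1 (TAZ/FOSL1), with 2 libraries per line and 12 in all. FOSL1 encodes FRA1, a subunit of the AP-1 transcription factor, and YAP and TAZ are the transcriptional coactivators at the end of the Hippo pathway. Total counts per library were 28124232 and 24914014 in EV, 25463205 and 28122599 in FOSL1, and 27392713 and 27568173 in YAP. They were 25268870 and 29668689 in TAZ, 27365329 and 25541006 in YAP/FOSL1, and 27814543 and 26554871 in TAZ/FOSL1. Mitochondrial genes took 9.94% and 10.1% of counts in EV, 11.8% and 11.5% in FOSL1, 13.3% and 12.1% in YAP/FOSL1, 11.3% and 10.7% in TAZ/FOSL1, 9.57% and 10.1% in YAP, and 9.49% and 10.1% in TAZ. Markers of other cell types were sparse, since of 30 such genes those above 1 CPM (library-scaled counts) in any library were COL6A1, COL6A2, COL1A1, ITGAM and PDGFRB. MIR30A, chosen after its values were seen, was counted 458 to 848 times in each EV and FOSL1 library and 0 times in the other 8. Changes are log2 fold changes ± standard error derived from the test, with n = 2 libraries per group. For gene lists, medians are of log2 fold changes and the adjusted p is that of camera. Where no further values are given, a list's count was the same adjusted over the list alone and its call held with an estimated correlation.

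Each transgene was high in the lines meant to carry it. FOSL1 (ENSG00000175592.4, chromosome 11, 65659520 to 65668044, minus strand, hg19) stood at 0.367 ± 0.23 CPM (mean ± SD, n = 2) in EV, from 15 and 5 counts. It reached 1070 ± 9.9 CPM in the FOSL1 line, 500 ± 50 CPM in YAP/FOSL1 and 1470 ± 28 CPM in TAZ/FOSL1, and its change against EV was 11.46 ± 0.16 (adjusted p = 2.4e-17), 10.35 ± 0.16 and 11.91 ± 0.16. With 1 library left out these changes ranged from 10.96 to 12.34, 9.86 to 11.24 and 11.42 to 12.80. Relative to the FOSL1 line, FOSL1 RNA differed by -1.10 ± 0.08 (adjusted p = 1e-07) in YAP/FOSL1 and by 0.46 ± 0.08 (adjusted p = 9e-04) in TAZ/FOSL1. YAP1 (ENSG00000137693.9, chromosome 11, 101981192 to 102104154, plus strand) rose by 2.86 ± 0.07 (adjusted p = 5.7e-16) in YAP and by 2.65 ± 0.07 (adjusted p = 5.5e-16) in YAP/FOSL1. WWTR1, which encodes TAZ (ENSG00000018408.10, chromosome 3, 149235022 to 149454501, minus strand), rose by 7.14 ± 0.11 (adjusted p = 1.3e-16) in TAZ and by 6.72 ± 0.11 (adjusted p = 4.8e-17) in TAZ/FOSL1. In the FOSL1 line, which carries neither of these transgenes, YAP1 rose by 0.40 ± 0.07 (adjusted p = 8.7e-05) and WWTR1 changed by -1.15 ± 0.14 (adjusted p = 5.2e-06).

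**Figure D1:**
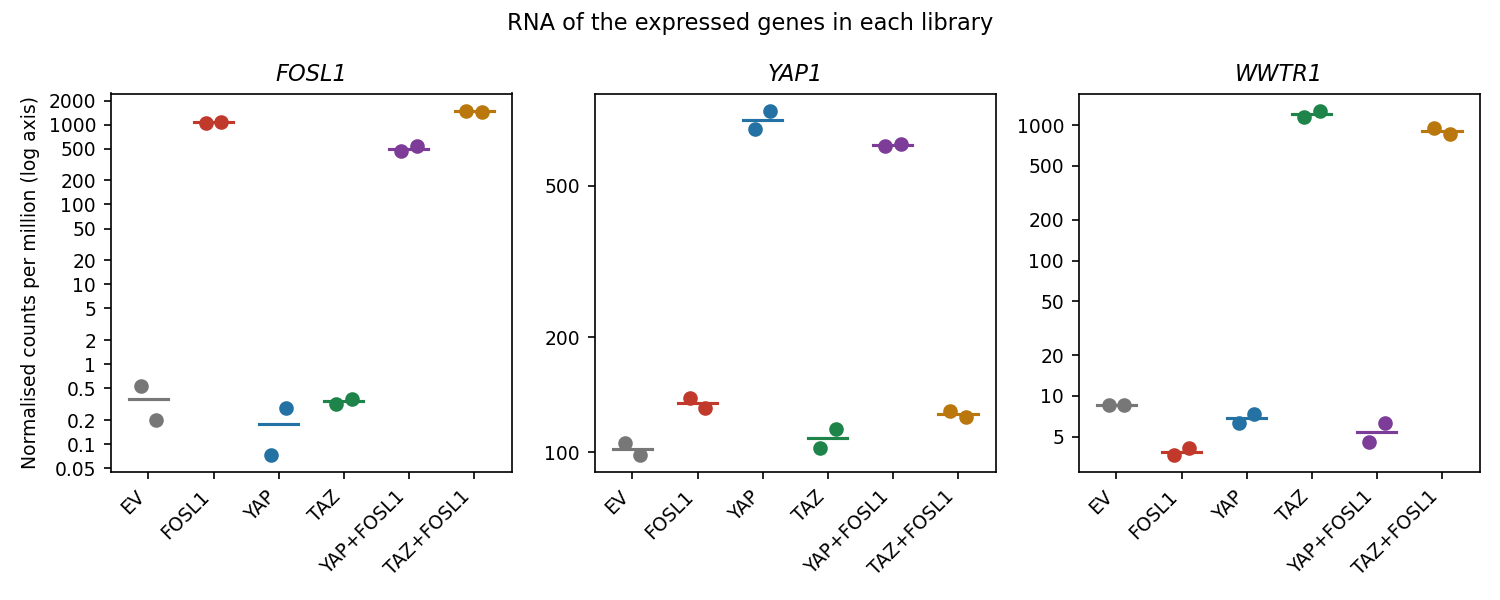
Normalised counts (CPM, log axis) of FOSL1, YAP1 and WWTR1 in each of the 12 libraries, with points for libraries and a line for the mean of each line's 2 libraries. FOSL1 averaged 1070 CPM in the FOSL1 line, 500 CPM in YAP/FOSL1 and 1470 CPM in TAZ/FOSL1.

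The comparison of FOSL1 with EV asks what FOSL1 does to LNCaP transcription. Genes of basal epithelium rose steeply. LAMB3 (ENSG00000196878.8, chromosome 1, 209788215 to 209825811), a chain of a basement membrane laminin, rose by 6.11 ± 0.12 (adjusted p = 5e-18). KRT15 (ENSG00000171346.9, chromosome 17, 39669995 to 39678781), a basal keratin, rose by 7.17 ± 0.24 (adjusted p = 9.1e-15), from 7 and 3 counts in EV to 705 and 784. ANKRD1 (ENSG00000148677.6, chromosome 10, 92671853 to 92681033), a widely used YAP and TAZ target, rose by 4.86 ± 0.14 (adjusted p = 7.5e-16), and EMP1, an epithelial membrane protein, by 5.58 ± 0.20 (adjusted p = 3.4e-14). Among the steepest falls were those of BCHE, which encodes butyrylcholinesterase (-3.48 ± 0.14, adjusted p = 1.8e-13), SI, the intestinal sucrase-isomaltase (-3.16 ± 0.17), MMP16, a membrane-bound metalloproteinase (-2.44 ± 0.10), and DDC, the aromatic amino acid decarboxylase (-2.13 ± 0.11). KLK3, which encodes prostate-specific antigen, stood at 0.01 ± 0.05 (adjusted p = 0.9), whereas TMPRSS2, another protease gene, rose by 1.00 ± 0.05 (adjusted p = 9.5e-12). KRT8, a luminal keratin, rose by 1.14 ± 0.14 (adjusted p = 0.00014), CD44 stood at 0.74 ± 0.42 (adjusted p = 0.18) and SYP, a neuroendocrine marker, at 0.08 ± 0.50 (adjusted p = 0.92). In all 7872 of 19351 genes changed, 4119 up and 3753 down, with 1449 up and 496 down at least 2-fold. A test against a fold of 1.5, chosen after the data were seen, passed 1881.

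Several of the lists moved as groups in the FOSL1 line. All 30 cell cycle genes fell, among them the mitotic kinase gene CDK1 (-1.33 ± 0.06, adjusted p = 7.1e-13), CCNB2 (-1.36 ± 0.06) and TOP2A (-1.23 ± 0.06), with a median of -1.16 (adjusted p = 3.6e-49). Among 17 basal epithelial markers 15 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 2.74 (adjusted p = 3.9e-23), led by LAMB3, KRT15 and TRIM29 (3.67 ± 0.13). All 10 NF-kappaB inflammatory genes rose (median 2.13, adjusted p = 1.4e-12), including the apoptosis inhibitor gene BIRC3 (3.90 ± 0.10, adjusted p = 1.5e-16), TNFAIP3 (1.99 ± 0.12) and NFKB2 (1.11). Among 17 YAP/TAZ targets 13 rose and 3 fell, including MYOF (4.32 ± 0.13), GADD45A (1.75) and CCN1 (0.64 ± 0.10, adjusted p = 1.9e-05), with a median of 0.73 (adjusted p = 1.2e-11). CCN2, another target, was counted 2 and 0 times in EV and 20 and 20 times in FOSL1. Among 19 interferon-stimulated genes 16 rose and 0 fell, with IFIT2 at 2.07 ± 0.18 and OASL at 2.75 ± 0.29 (median 1.37, adjusted p = 4.5e-06). Among 25 actin cytoskeleton and focal adhesion genes 19 rose and 2 fell (19 and 3 adjusted over the list alone), with TPM4 at 0.75 (median 0.75, adjusted p = 1.6e-08). Among 16 mesenchymal transition genes 11 rose and 1 fell, with VIM, which encodes vimentin, at 1.66 ± 0.16 and TNC, tenascin C, at 4.08 ± 0.31 (median 0.72, adjusted p = 2e-04). Of 14 invasion genes linked to AP-1 10 rose and 1 fell, with the matrix metalloproteinase gene MMP7 at 4.70 ± 0.26 (adjusted p = 1.4e-11), from 7 and 7 counts in EV (median 2.01, adjusted p = 2e-04). Of 9 stem cell markers 4 rose and 0 fell (4 and 1 adjusted over the list alone), with the transcription factor genes SOX9 at 2.84 ± 0.12 and KLF4 at 2.69 ± 0.14 (median 0.74, adjusted p = 3e-05).

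Of 14 other AP-1 members 7 rose and 1 fell (8 and 1 adjusted over the list alone), with FOSL2 at 2.81 ± 0.07 (adjusted p = 5.7e-17), MAF at 1.54 ± 0.05 and JUN at 0.78 ± 0.10 (median 0.41, adjusted p = 1.8e-05, adjusted p = 0.078 with an estimated correlation). Of 18 genes of the unfolded protein and amino acid stress response 1 rose and 10 fell, with the asparagine synthetase gene ASNS at -1.09 ± 0.06 (adjusted p = 3.1e-11) and XBP1 at -0.61 (median -0.35, adjusted p = 5.9e-05, adjusted p = 0.078 with an estimated correlation). The remaining lists that are reported here were not called. Of 19 luminal prostate markers 7 rose and 6 fell (adjusted p = 0.24). Of 7 neuroendocrine markers 2 rose and 0 fell (adjusted p = 0.24). Of 21 Hippo pathway and TEAD factors 7 rose and 5 fell (adjusted p = 0.45). Of 19 cholesterol synthesis genes 4 rose and 5 fell (4 and 7 adjusted over the list alone, adjusted p = 0.79). Of 17 hypoxia and glycolysis genes 5 rose and 4 fell, where EGLN3 at 3.01 ± 0.07 and LDHA at -0.74 went apart (adjusted p = 0.27). Of 4 fibroblast markers 2 rose and 1 fell, with COL6A2 at 1.14 ± 0.15 (adjusted p = 0.37). Of 4 immune cell markers 1 rose and 0 fell, the integrin gene ITGAM at 4.01 ± 0.39 (adjusted p = 0.24). Of 12 heat shock and handling stress genes 2 rose and 4 fell (3 and 4 adjusted over the list alone), with a median of 0.07 and a mean of 0.06. The test, which sets their test statistics against those of all other genes, pointed down (adjusted p = 0.65).

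**Figure D2:**
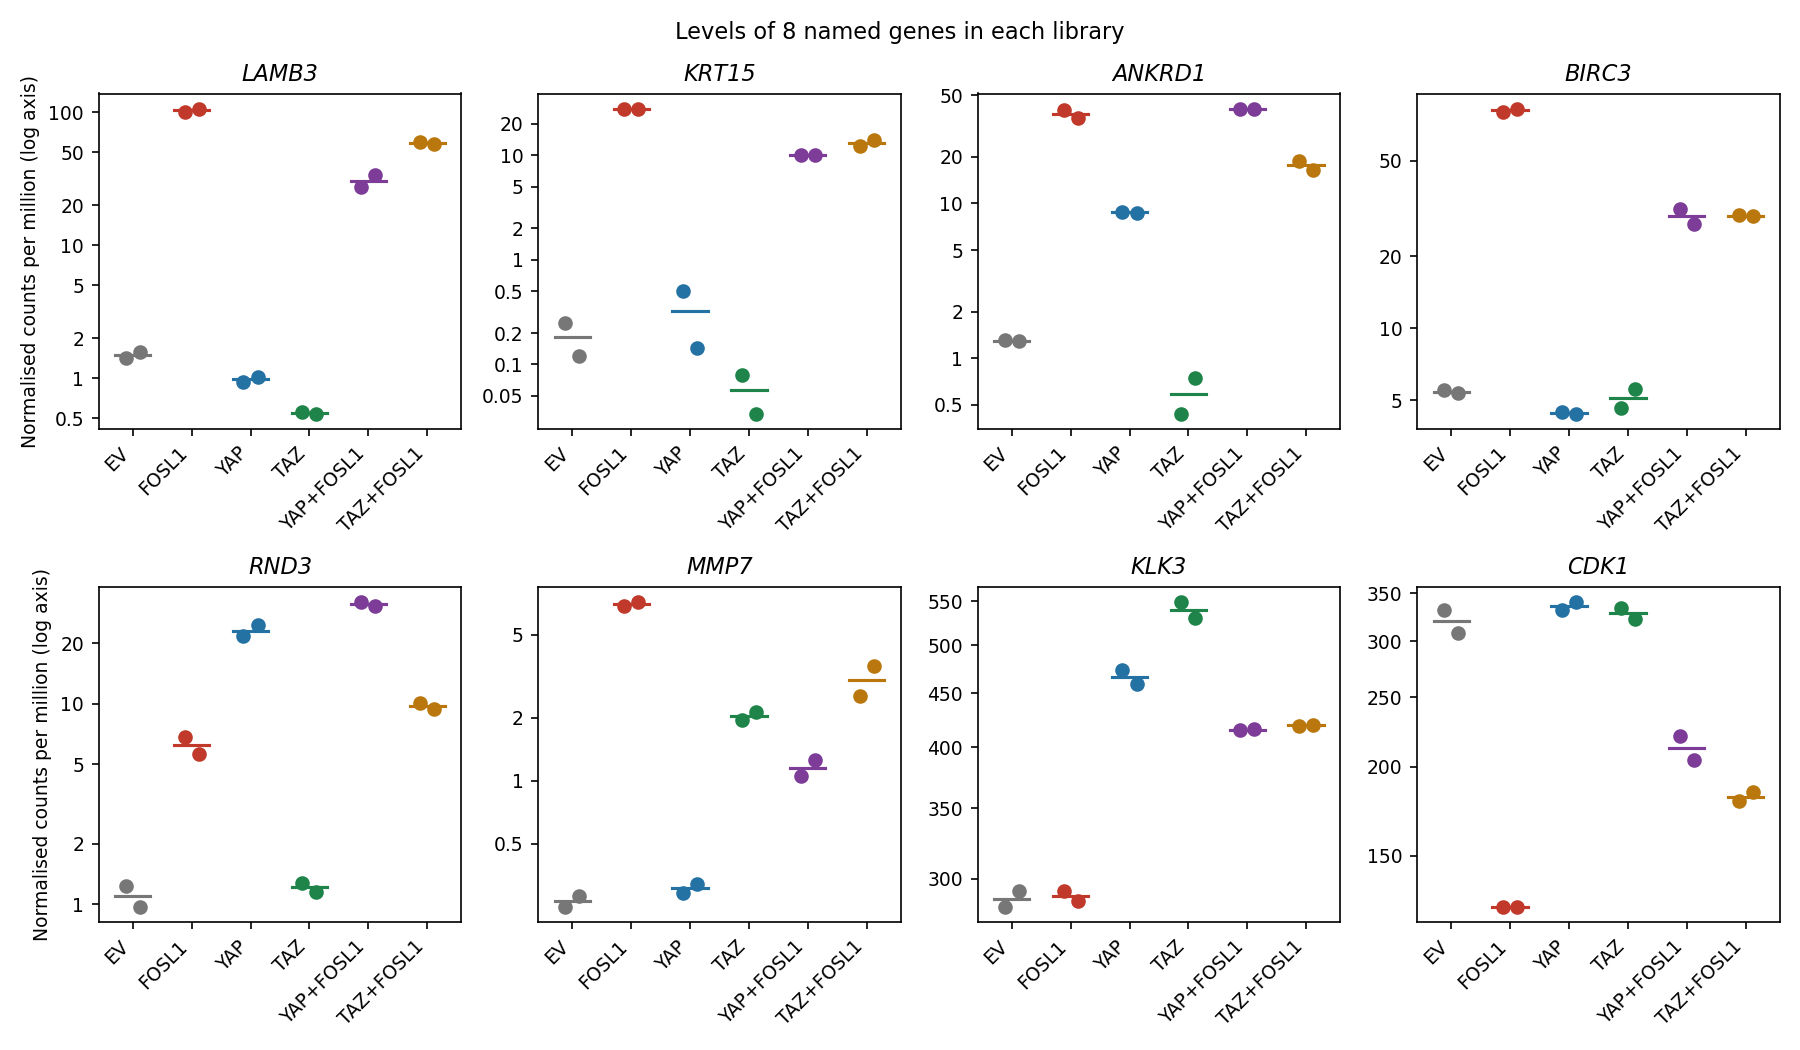
Normalised counts (CPM, log axis) of LAMB3, KRT15, ANKRD1, BIRC3, RND3, MMP7, KLK3 and CDK1 in the 12 libraries, with points for libraries and a line for each line's mean. LAMB3, KRT15, BIRC3 and MMP7 were higher and CDK1 lower in both FOSL1 libraries than in both EV libraries.

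**Figure D3:**
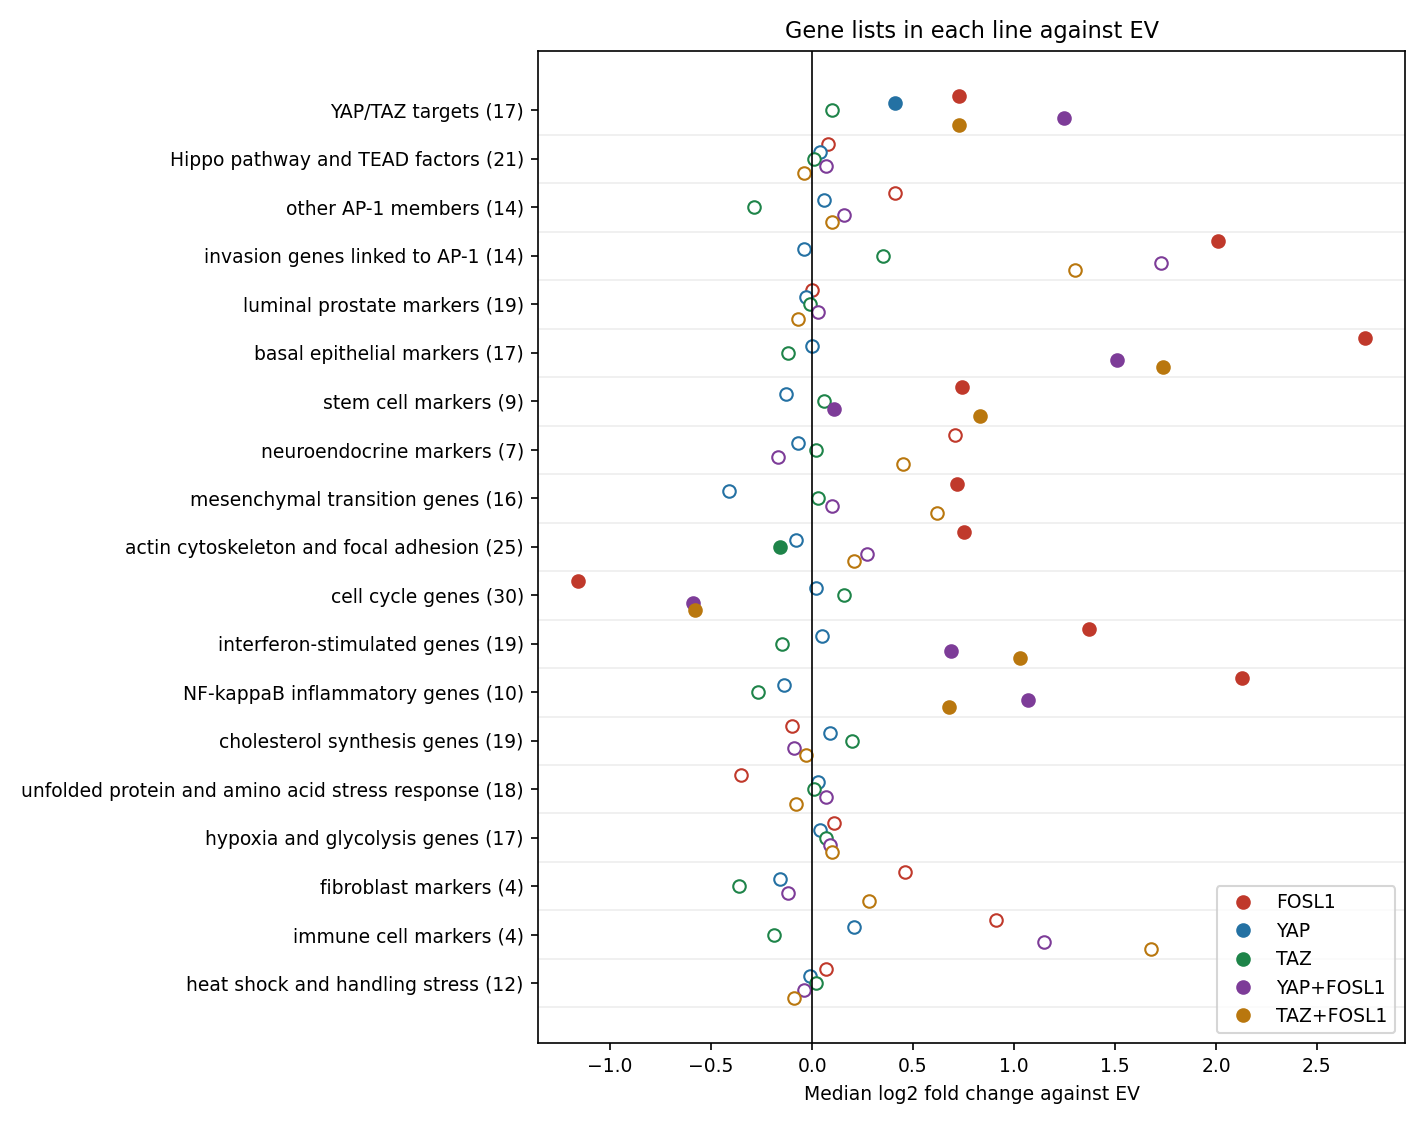
Median log2 fold change against EV of 19 gene lists (number of tested members in brackets) in the 5 lines, with filled points for lists called with both the preset and an estimated correlation. The cell cycle list lay at -1.16 in FOSL1 and -0.59 in YAP/FOSL1, and the basal list at 2.74 in FOSL1.

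YAP against EV compares the line carrying the coactivator alone with the control line. RND3 (ENSG00000115963.9, chromosome 2, 151324709 to 151395525) rose by 4.38 ± 0.15 (adjusted p = 2.2e-13). SDC2, a syndecan gene, rose by 4.01 ± 0.09 (adjusted p = 5.3e-17), RGS16, a regulator of G protein signalling, by 4.24 ± 0.26, and the transcription factor gene RUNX1 by 3.24 ± 0.21. DAPK1, a death-associated kinase gene, fell by 2.98 ± 0.25 (adjusted p = 1.3e-07), and ADRA2A, an adrenergic receptor gene, by 2.79 ± 0.23 (adjusted p = 6.9e-08). BMPR1B, a receptor for bone morphogenetic proteins, changed by -1.77 ± 0.13. KLK3 rose by 0.70 ± 0.05 (adjusted p = 3.5e-08) and TMPRSS2 by 0.64 ± 0.05 (adjusted p = 1.2e-07). In the list of 17 YAP/TAZ targets 8 rose and 0 fell (11 and 0 adjusted over the list alone), among them ANKRD1 (2.75 ± 0.16, adjusted p = 5.6e-10), AMOTL2 (1.72 ± 0.17), CCN1 (1.41 ± 0.09, adjusted p = 3.7e-09) and PTPN14 (1.23 ± 0.08), with a median of 0.41 (adjusted p = 1.8e-16). CCN2 was counted 27 and 13 times in YAP against 2 and 0 in EV. Of 16 mesenchymal transition genes 0 rose and 7 fell (1 and 7 adjusted over the list alone), with VIM at -1.84 ± 0.24 (adjusted p = 2.4e-05) and the fibronectin gene FN1 at -0.61 ± 0.07 (median -0.41, adjusted p = 0.00042, adjusted p = 0.11 with an estimated correlation). No gene of the other AP-1 members changed, and 1 cell cycle gene did (0 adjusted over the list alone; adjusted p = 0.88 for each list). Some called lists were not called in every fit with 1 library left out. Of 18 genes of the unfolded protein and amino acid stress response 7 rose and 1 fell (8 and 5 adjusted over the list alone), with HERPUD1 at 0.57 ± 0.05 (median 0.03, adjusted p = 0.01, adjusted p = 0.33 with an estimated correlation), and the adjusted p was 0.21 without YAP replicate 1. Of 21 Hippo pathway and TEAD factors 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.04, adjusted p = 0.016, adjusted p = 0.33 with an estimated correlation), and the adjusted p was 0.065 without EV replicate 2, 0.078 without YAP replicate 2 and 0.073 with no filter on low counts. Of 25 actin cytoskeleton and focal adhesion genes 0 rose and 6 fell, with TPM4 at -0.59 ± 0.06 (median -0.08, adjusted p = 0.018, adjusted p = 0.33 with an estimated correlation), and the adjusted p was 0.065 without EV replicate 2 and 0.23 without YAP replicate 1. Of 19 cholesterol synthesis genes 4 rose and 0 fell (median 0.09, adjusted p = 0.018, adjusted p = 0.33 with an estimated correlation), and the adjusted p was 0.05 without EV replicate 2 and 0.39 without YAP replicate 1. In all 1567 genes changed, 847 up and 720 down, with 173 up and 134 down at least 2-fold. The number was 644 without EV replicate 1, 732 without EV replicate 2 and 1002 without YAP replicate 2, and 182 genes passed the test against a fold of 1.5. Median, mean and test did not share a sign for the invasion, luminal, neuroendocrine and interferon lists, none of which was called.

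TAZ against EV gave a response of similar size in gene number. DDC rose by 2.58 ± 0.08 (adjusted p = 3.6e-14), MMP7 by 2.93 ± 0.32 (adjusted p = 4.2e-06) from 7 and 7 counts in EV, ADTRP by 1.85 ± 0.29 and the cerebellin gene CBLN2 by 1.69 ± 0.08. TMEFF2, a transmembrane protein gene abundant in prostate, changed by -2.20 ± 0.13 (adjusted p = 8.1e-10), FLRT2 by -2.42 ± 0.23 and BMPR1B by -1.87. KLK3 rose by 0.91 ± 0.05 (adjusted p = 6.1e-10), whereas TMPRSS2 stood at -0.06 ± 0.05 (adjusted p = 0.61). Among 25 actin cytoskeleton and focal adhesion genes 0 rose and 9 fell (0 and 10 adjusted over the list alone), with TPM4 at -0.91 ± 0.06 (adjusted p = 4.9e-09) and ACTA2 at -1.06 (median -0.16, adjusted p = 7.6e-08). YAP/TAZ targets were split, since of 17 tested 2 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.24 for the list, median 0.10 and mean -0.04). CCN1 rose by 0.71 ± 0.10 (adjusted p = 5.7e-05) and CRIM1 by 1.07 ± 0.16 (adjusted p = 0.00019). ANKRD1 changed by -1.10 ± 0.27 (adjusted p = 0.012) and AMOTL2 by -1.23 ± 0.23 (adjusted p = 0.0016), but the adjusted p of ANKRD1 was 0.084 without EV replicate 1, 0.072 without EV replicate 2 and 0.15 without TAZ replicate 1, and that of AMOTL2 was 0.057 without EV replicate 2. Among 30 cell cycle genes 8 rose and 0 fell (16 and 0 adjusted over the list alone), with RRM2 at 0.36 ± 0.06 and CCND1 at 0.30 ± 0.05 (median 0.16, adjusted p = 2.1e-06, adjusted p = 0.08 with an estimated correlation). Of 14 other AP-1 members 0 rose and 4 fell (0 and 7 adjusted over the list alone), with MAF at -1.31 ± 0.06 (adjusted p = 5.2e-12) and FOSL2 at -0.55 ± 0.07 (median -0.29, adjusted p = 7.4e-06, adjusted p = 0.12 with an estimated correlation). Of 19 cholesterol synthesis genes 5 rose and 0 fell (9 and 0 adjusted over the list alone), with INSIG1 at 0.54 ± 0.06 (median 0.20, adjusted p = 0.00034, adjusted p = 0.12 with an estimated correlation). Of 17 basal epithelial markers 1 rose and 2 fell (2 and 4 adjusted over the list alone), with LAMB3 at -1.43 ± 0.27 (adjusted p = 0.0015), a median of -0.12 or, with genes at 0 counts set to their bound, -0.23, and a mean of 0.18 (adjusted p = 0.41). In all 1561 genes changed, 863 up and 698 down, with 104 up and 138 down at least 2-fold. The number was 703 without EV replicate 1, 669 without EV replicate 2 and 884 without TAZ replicate 2, and 125 genes passed the test against a fold of 1.5. The stem cell, neuroendocrine and mesenchymal lists, not called, also had a median, mean and test that differed in sign.

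YAP and TAZ are paralogs, and their lines differed directly in 1387 genes, 745 higher in YAP and 642 higher in TAZ. RND3 was higher in YAP by 4.26 ± 0.15 (adjusted p = 1.9e-13), ANKRD1 by 3.85 ± 0.18 (adjusted p = 1.8e-11), SDC2 by 3.24 ± 0.08 and RGS16 by 3.68. NR2F1, an orphan nuclear receptor gene, differed by -3.34 ± 0.23 (adjusted p = 4.5e-09), MMP7 by -2.72 ± 0.31 and TRPM8, a cation channel gene of prostate, by -1.62 ± 0.12, all higher in TAZ. Of 17 YAP/TAZ targets 7 were higher and 1 lower in YAP (9 and 2 adjusted over the list alone), with AMOTL2 at 2.95 ± 0.19, PTPN14 at 1.45 ± 0.08 and a median of 0.22 (adjusted p = 9.1e-11). Of 14 other AP-1 members 4 were higher (5 adjusted over the list alone; median 0.24, adjusted p = 1e-06, adjusted p = 0.12 with an estimated correlation). Within the 30 cell cycle genes 7 were lower in YAP (17 adjusted over the list alone; median -0.16, adjusted p = 1.1e-05, adjusted p = 0.11 with an estimated correlation). The number of genes was 883 without TAZ replicate 1, 830 without TAZ replicate 2, 546 when the other groups were left out of the fit and 166 in the test against a fold of 1.5.

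The double lines were compared with EV next. In YAP/FOSL1, ANKRD1 rose by 4.97 ± 0.14 (adjusted p = 6.9e-16), KRT15 by 5.70 ± 0.28, RND3 by 4.81 ± 0.15 and LAMB3 by 4.35 ± 0.13. SI changed by -2.66 ± 0.16, DAPK1 by -2.62 and BCHE by -2.21. KLK3 rose by 0.53 ± 0.05 (adjusted p = 2.1e-07) and TMPRSS2 by 1.24 ± 0.05. CCN2 was counted 52 and 54 times, and the transcription factor gene MEF2C 80 and 77 times, each against 2 and 0 in EV. Among 17 YAP/TAZ targets 12 rose and 2 fell (13 and 2 adjusted over the list alone), with CCN1 at 1.44 ± 0.09 (median 1.25, adjusted p = 2.9e-19). Among 17 basal markers 12 rose and 0 fell (median 1.51, adjusted p = 1.7e-16). Of 30 cell cycle genes 0 rose and 28 fell (0 and 29 adjusted over the list alone), with CCNB1 at -0.86 ± 0.07 (median -0.59, adjusted p = 2.3e-25). Among 10 NF-kappaB genes 8 rose and 0 fell, with BIRC3 at 2.44 ± 0.10 (median 1.07, adjusted p = 8e-06). Of 19 interferon-stimulated genes 10 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.69, adjusted p = 0.0061). In all 6132 genes changed, 3272 up and 2860 down, with 949 up and 266 down at least 2-fold, and 919 passed the test against a fold of 1.5.

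In TAZ/FOSL1, LAMB3 rose by 5.30 ± 0.13 (adjusted p = 7.8e-17) against EV, KRT15 by 6.08 ± 0.26, ANKRD1 by 3.75 ± 0.15 (adjusted p = 1.3e-13) and MMP7 by 3.50 ± 0.30. MEF2C was counted 264 and 276 times against 2 and 0 in EV. SI changed by -3.36 ± 0.17, FLRT2 by -3.15, BCHE by -3.14 and MMP16 by -2.99. KLK3 rose by 0.55 ± 0.05, TMPRSS2 by 0.56 ± 0.05 and CCN1 by 0.53 ± 0.10. In the list of 17 YAP/TAZ targets 12 rose and 1 fell (median 0.73, adjusted p = 6.8e-07). Of 17 basal markers 13 rose and 1 fell (median 1.74, adjusted p = 5.3e-17). Among 30 cell cycle genes 0 rose and 29 fell (0 and 30 adjusted over the list alone), with CDK1 at -0.82 ± 0.06 (adjusted p = 1.3e-09; list median -0.58, adjusted p = 1.7e-20). Of 10 NF-kappaB genes 8 rose and 0 fell, with BIRC3 at 2.44 ± 0.10 (median 0.68, adjusted p = 6.4e-05). Among 19 interferon-stimulated genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 1.03, adjusted p = 0.00037). Of 9 stem cell markers 4 rose and 0 fell, with SOX9 at 2.77 (median 0.83, adjusted p = 0.00021). Among 16 mesenchymal transition genes 8 rose and 3 fell, with TNC at 5.10 (median 0.62, adjusted p = 0.0044, adjusted p = 0.095 with an estimated correlation). Among 18 stress response genes 2 rose and 7 fell (median -0.08, adjusted p = 0.0018, adjusted p = 0.18 with an estimated correlation). In all 6754 genes changed, 3470 up and 3284 down, with 1201 up and 345 down at least 2-fold, and 1216 passed the test against a fold of 1.5.

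Each double line was then compared with its single lines, and whether it was derived from them was not established here. In YAP/FOSL1 against YAP, LAMB3 was higher by 4.94 ± 0.14 (adjusted p = 3e-15), KRT15 by 4.93 ± 0.25 and ANKRD1 by 2.22 ± 0.10 (adjusted p = 3.6e-12). BCHE changed by -1.85 ± 0.12 and MMP16 by -1.63. Within the 30 cell cycle genes 0 rose and 28 fell (0 and 30 adjusted over the list alone), with the polo-like kinase gene PLK1 at -0.82 and the replication helicase gene MCM2 at -0.82 (median -0.59, adjusted p = 1.9e-35). Among 17 basal markers 13 rose and 0 fell (13 and 1 adjusted over the list alone, median 1.96, adjusted p = 2.6e-19), where the median was 1.64 with genes at 0 counts set to their bound. All 10 NF-kappaB genes rose, with BIRC3 at 2.73 ± 0.11 (median 1.39, adjusted p = 8.2e-10). Of 17 YAP/TAZ targets 9 rose and 1 fell (9 and 2 adjusted over the list alone), with MYOF at 2.50 (median 0.26, adjusted p = 2.3e-07). Of 25 actin cytoskeleton genes 14 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.38, adjusted p = 2.1e-05). Of 16 mesenchymal transition genes 8 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.45, adjusted p = 0.00038). In all 4553 genes changed, 2530 up and 2023 down, against 2354 when the other groups were left out of the fit and 574 in the test against a fold of 1.5.

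In TAZ/FOSL1 against TAZ, LAMB3 was higher by 6.73 ± 0.15 (adjusted p = 1.9e-17), KRT15 by 7.78 ± 0.32 and ANKRD1 by 4.86 ± 0.17 (adjusted p = 1.6e-14). BCHE changed by -3.50 ± 0.13, MMP16 by -3.36 and CBLN2 by -2.96, and KLK3 fell by 0.36 ± 0.05 (adjusted p = 1.8e-05). All 30 cell cycle genes fell, with CCNB1 at -0.97 (median -0.74, adjusted p = 1.3e-29). Of 17 basal markers 14 rose and 2 fell (median 1.96, adjusted p = 9.2e-17). Among 10 NF-kappaB genes 9 rose and 0 fell, with BIRC3 at 2.52 ± 0.10 (median 1.05, adjusted p = 5e-06). Of 19 interferon-stimulated genes 14 rose and 0 fell (median 0.93, adjusted p = 0.00029). Among 17 YAP/TAZ targets 8 rose and 2 fell (median 0.48, adjusted p = 6e-05). Of 18 stress response genes 0 rose and 11 fell (0 and 12 adjusted over the list alone, median -0.31, adjusted p = 4.8e-05, adjusted p = 0.083 with an estimated correlation). In all 7185 genes changed, 3622 up and 3563 down, and 1327 passed the test against a fold of 1.5.

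The response to FOSL1 was smaller where YAP or TAZ was also expressed. FOSL1 RNA itself was lower in YAP/FOSL1 than in the FOSL1 line and higher in TAZ/FOSL1. Across 13074 genes, the change in YAP/FOSL1 against YAP followed that in FOSL1 against EV with a slope of 0.60 (95% interval over genes 0.59 to 0.61, corrected for noise by split replicates) and a correlation of 0.85, where 1 would be an equal response. In TAZ/FOSL1 against TAZ the slope was 0.86 (0.84 to 0.88) and the correlation 0.91. Slopes from single libraries, 16 for each line, were 0.55 to 0.65 with YAP and 0.84 to 0.89 with TAZ. These are relations across genes, which are not independent replicates, and the pairs share no library. Of 4119 genes that FOSL1 raised, 2187 also rose and 5 fell in YAP/FOSL1 against YAP, and 2942 rose and 14 fell in TAZ/FOSL1 against TAZ. Of 3753 genes that FOSL1 lowered, 1546 also fell and 8 rose with YAP, and 2720 fell and 8 rose with TAZ.

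**Figure D4:**
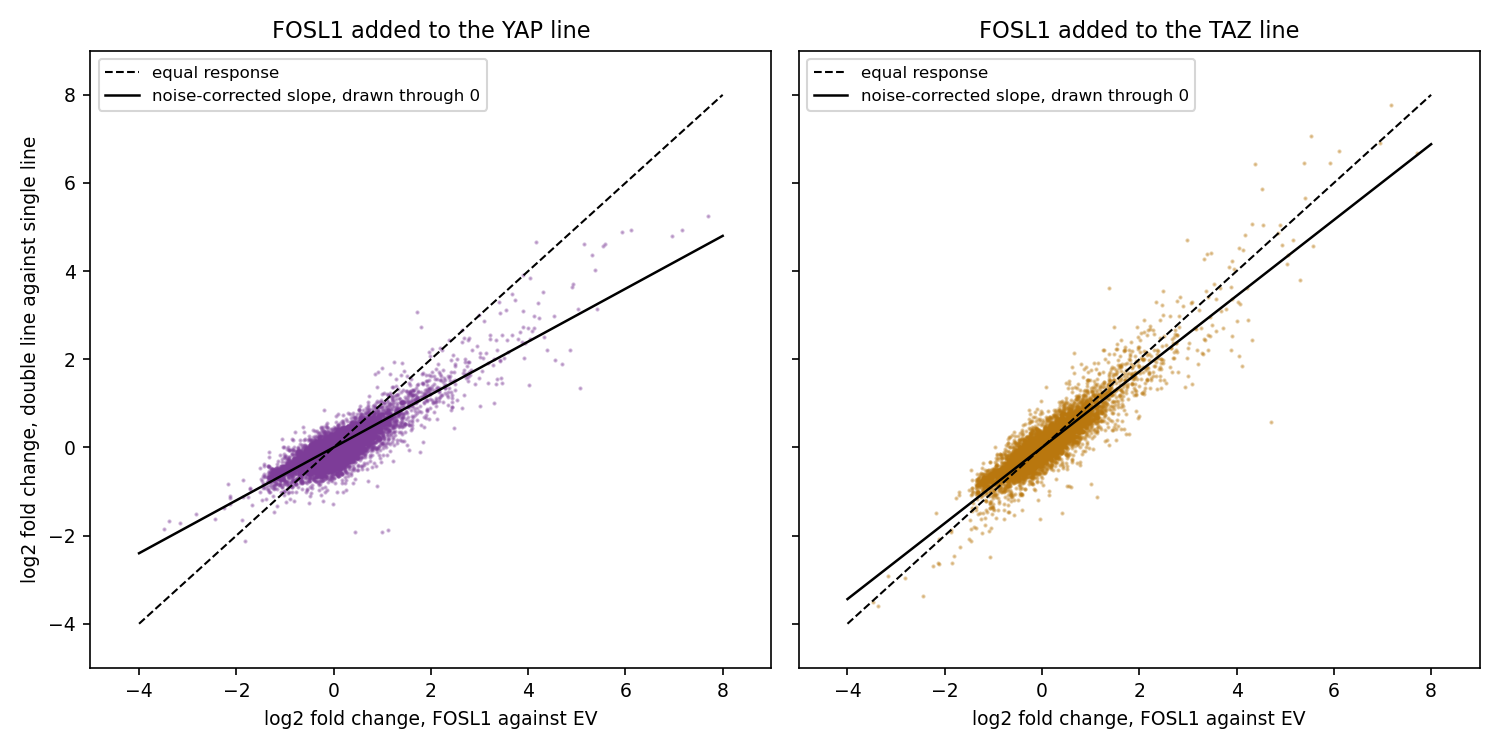
Log2 fold change of each gene in FOSL1 against EV (x axis) and in YAP/FOSL1 against YAP or TAZ/FOSL1 against TAZ (y axis), 1 point per gene, with a dashed line for an equal response and a solid line for the noise-corrected slope. The slope was 0.60 with YAP and 0.86 with TAZ.

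In YAP/FOSL1 against FOSL1, RGS16 was higher by 5.51 ± 0.29 (adjusted p = 7.4e-11), DDC by 2.54 ± 0.11, CBLN2 by 2.48 and KLK3 by 0.52 ± 0.05 (adjusted p = 6e-07). LAMB3 changed by -1.76 ± 0.08 (adjusted p = 2.1e-11), KRT15 by -1.48 ± 0.13, MMP7 by -2.60 ± 0.20 (adjusted p = 1.1e-08), DAPK1 by -2.73 ± 0.24 and VIM by -2.21 ± 0.17. FOSL1 RNA itself was lower here, as given with the transgenes. Of 30 cell cycle genes 28 rose and 0 fell (29 and 0 adjusted over the list alone), with RRM2 at 0.88 ± 0.06 and CDK1 at 0.74 ± 0.06 (median 0.48, adjusted p = 2.8e-27). Among 17 basal markers 2 rose and 12 fell (median -0.79, adjusted p = 3.8e-11). Of 10 NF-kappaB genes 0 rose and 8 fell (0 and 9 adjusted over the list alone), with BIRC3 at -1.46 ± 0.08 (adjusted p = 1.7e-10; list median -0.73, adjusted p = 5.8e-10). Among 19 interferon-stimulated genes 0 rose and 10 fell (0 and 11 adjusted over the list alone, median -0.79, adjusted p = 0.00013). Among 25 actin cytoskeleton genes 1 rose and 16 fell (1 and 19 adjusted over the list alone, median -0.41, adjusted p = 9.5e-11). Among 16 mesenchymal transition genes 0 rose and 8 fell (0 and 9 adjusted over the list alone, median -0.53, adjusted p = 4.1e-07). Among 18 stress response genes 13 rose and 0 fell, with HERPUD1 at 0.76 ± 0.06 (median 0.32, adjusted p = 2.2e-09). YAP/TAZ targets went both ways, since 3 rose and 3 fell of 17 (adjusted p = 0.9), with CCN1 at 0.80 ± 0.09 and MYOF at -1.40. In all 4595 genes changed, 2289 up and 2306 down. The number was 2909 without FOSL1 replicate 1, 2429 without FOSL1 replicate 2, 2981 without YAP/FOSL1 replicate 1 and 388 in the test against a fold of 1.5.

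In TAZ/FOSL1 against FOSL1, FRAS1 was higher by 2.44 ± 0.11, TRPM8 by 2.19 ± 0.12 and KLK3 by 0.54 ± 0.05. MEF2C rose by 3.34 ± 0.24 (adjusted p = 1.2e-08), from 22 and 30 counts in FOSL1 to 264 and 276. ANKRD1 changed by -1.10 ± 0.09 (adjusted p = 8.1e-08), LAMB3 by -0.81 ± 0.08, TRIM29 by -1.13 and TMPRSS2 by -0.44 ± 0.05. In the list of 17 YAP/TAZ targets 1 rose and 7 fell (2 and 8 adjusted over the list alone), with MYOF at -1.45 (median -0.21, adjusted p = 3.4e-07). Of 25 actin cytoskeleton genes 0 rose and 17 fell (0 and 21 adjusted over the list alone), with TPM4 at -0.79 ± 0.06 (median -0.48, adjusted p = 1.5e-17). Of 17 basal markers 1 rose and 11 fell (median -0.81, adjusted p = 7.2e-10). Of 14 other AP-1 members 0 rose and 8 fell (0 and 10 adjusted over the list alone, median -0.57, adjusted p = 5e-09). Among 10 NF-kappaB genes 0 rose and 8 fell (1 and 8 adjusted over the list alone), with BIRC3 at -1.46 ± 0.08 (median -0.80, adjusted p = 5.8e-13). Among 30 cell cycle genes 27 rose and 0 fell, with RRM2 at 0.75 ± 0.06 and TOP2A at 0.64 (median 0.51, adjusted p = 9.2e-38). In all 3093 genes changed, 1389 up and 1704 down. The number was 1699 without FOSL1 replicate 1, 1649 without FOSL1 replicate 2, 1699 without TAZ/FOSL1 replicate 1, 1698 without TAZ/FOSL1 replicate 2, 5983 with the other groups left out of the fit and 247 in the test against a fold of 1.5.

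The double lines differed from each other in 2804 genes, 1557 higher in YAP/FOSL1 and 1247 higher in TAZ/FOSL1. RGS16 was higher in YAP/FOSL1 by 6.36 ± 0.32 (adjusted p = 5.5e-11), SDC2 by 2.83 ± 0.08, PTPN14 by 1.37, ANKRD1 by 1.21 ± 0.09 and CCN1 by 0.91 ± 0.09. TRPM8 (-2.33 ± 0.12), TNC (-1.10) and the transcription factor gene SNAI2 (-0.96) were higher in TAZ/FOSL1, and KLK3 stood at -0.02 ± 0.05 (adjusted p = 0.89). Of 17 YAP/TAZ targets 7 were higher and 3 lower in YAP/FOSL1 (median 0.19, adjusted p = 4.6e-07). Of 18 stress response genes 8 were higher (11 higher and 1 lower adjusted over the list alone), with HSPA5 at 0.50 ± 0.06 (median 0.24, adjusted p = 2.9e-05, adjusted p = 0.22 with an estimated correlation). The cell cycle list, with 2 members higher and 3 lower, was not called (adjusted p = 0.83). The number of genes was 1410 without TAZ/FOSL1 replicate 1, 1253 without TAZ/FOSL1 replicate 2, 1699 without YAP/FOSL1 replicate 1, 1830 with the other groups left out of the fit and 215 in the test against a fold of 1.5.

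The interaction asks whether the response to FOSL1 differed where YAP was expressed. FOSL1 RNA in YAP/FOSL1 was 0.466 times that of the FOSL1 line, so a lower dose and an effect of YAP cannot be told apart here. ANKRD1 was lower in YAP/FOSL1 than the sum of the single effects, with an interaction of -2.64 ± 0.19 (adjusted p = 7.6e-08), as were MMP7 (-2.81 ± 0.54), RUNX1 (-2.60 ± 0.26) and MYOF (-1.82). BCHE (1.63 ± 0.20, adjusted p = 5.5e-05), SI (1.44) and CBLN2 (1.30), which FOSL1 lowers, fell less with YAP. Within the 30 cell cycle genes 24 had a positive interaction and 0 a negative one (26 and 0 adjusted over the list alone), with TOP2A at 0.72 ± 0.08 and a median of 0.50 (adjusted p = 7.9e-34). Among 17 YAP/TAZ targets 7 had a negative one (9 adjusted over the list alone; median -0.46, adjusted p = 3.5e-12). Among 17 basal markers 6 had a negative one (7 adjusted over the list alone; median -0.99, adjusted p = 9.4e-06). Of 10 NF-kappaB genes 4 were negative, with BIRC3 at -1.17 ± 0.15 (5 adjusted over the list alone; median -0.63, adjusted p = 1.5e-05). In all 1312 genes passed, 671 positive and 641 negative. Of the 1270 that FOSL1 alone also changed, 1264 (99.5%) had the sign opposite to its effect, which is partly built in, since both values contain the FOSL1 and EV libraries. With no library shared, where 50% would be expected without a relation, 179 of 179 and 257 of 257 called genes were opposed. The number was 510 without EV replicate 1, 782 without EV replicate 2, 673 without FOSL1 replicate 1, 495 without FOSL1 replicate 2, 806 without YAP/FOSL1 replicate 1 and 2978 without YAP/FOSL1 replicate 2. It was 2002 with no filter on low counts and 48 in the test against a fold of 1.5.

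The interaction of TAZ with FOSL1 was called in 452 genes. MMP7 had an interaction of -4.14 ± 0.36 (adjusted p = 3.8e-06), MYOF of -1.88 ± 0.20, BIRC3 of -1.38 ± 0.15 and CCN1 of -0.83 ± 0.13 (adjusted p = 0.0018). GUCY1A2, a guanylate cyclase subunit gene, was positive at 2.23 ± 0.31 (adjusted p = 0.00044), and ANKRD1 was at 0.00 (adjusted p = 1). Of 30 cell cycle genes 18 were positive (27 positive and 1 negative adjusted over the list alone), with TOP2A at 0.51 ± 0.08 and a median of 0.38 (adjusted p = 1.1e-29). In the list of 17 YAP/TAZ targets 6 were negative (8 adjusted over the list alone; median -0.38, adjusted p = 7.7e-10). Of 14 invasion genes 2 were negative (5 adjusted over the list alone; median -0.95, adjusted p = 5e-07). Among 10 NF-kappaB genes 1 was negative (4 adjusted over the list alone; median -0.48, adjusted p = 5e-07). Of the 452 genes 214 were positive and 238 negative, and of the 404 that FOSL1 alone changed 325 (80.4%) were opposed to its effect, which is partly built in here too. With no library shared 20 of 32 and 25 of 37 were. The number was 138 without EV replicate 1, 192 without EV replicate 2, 155 without FOSL1 replicate 1, 127 without FOSL1 replicate 2, 276 without TAZ replicate 2, 169 without TAZ/FOSL1 replicate 1 and 173 without TAZ/FOSL1 replicate 2. It was 857 with the other groups left out of the fit and 11 in the test against a fold of 1.5.

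The responses against EV were compared with each other across genes, which are not independent replicates, for 10 pairs of lines. All use the same EV libraries, and unchanged groups that shared simulated EV libraries gave correlations of 0.501 to 0.513. The simulations drew new EV libraries at the mean of EV, so the deviations of the real ones are not in them. Their spread was that over all lines, while EV replicates were quieter than those of YAP, TAZ and YAP/FOSL1. Simulated covariances may therefore be too high. Part of any excess may still come from the shared controls. FOSL1 and TAZ/FOSL1 correlated at 0.828 (simulated 0.507), with a covariance of 0.528 against a simulated 0.0532. They shared 5180 genes changed in the same direction, where 1380 would be expected by chance, and 57 in opposite directions. FOSL1 and YAP/FOSL1 correlated at 0.777 (simulated 0.501; covariance 0.465 against 0.053), with 4413 shared genes (1250 expected), and the double lines at 0.795 (simulated 0.504; covariance 0.434 against 0.053), with 4172 (1070 expected). YAP and YAP/FOSL1 correlated at 0.533 (simulated 0.506; covariance 0.189 against 0.0531), with 1058 genes in the same direction (250 expected) and 92 in opposite directions (247 expected). In some pairs the correlation was below the simulated one although the covariance was above it. TAZ and TAZ/FOSL1 correlated at 0.28 (simulated 0.512; covariance 0.0999 against 0.0534), with 601 in the same direction (273 expected) and 373 in opposite directions (272 expected). YAP and TAZ/FOSL1 correlated at 0.314 (simulated 0.511; covariance 0.118 against 0.0532), with 717 in the same direction (274 expected) and 268 in opposite directions (273 expected). The correlation was 0.26 (simulated 0.505; covariance 0.087 against 0.0532) for TAZ and YAP/FOSL1, with 608 in the same direction (249 expected) and 358 in opposite directions (246 expected). YAP and TAZ correlated at 0.495 (simulated 0.513), with a covariance of 0.115 against 0.0534 and 588 shared genes against 63.7 expected. FOSL1 and YAP correlated at 0.183 (simulated 0.508; covariance 0.0759 against 0.0531), with 612 genes in the same direction (320 expected) and 393 in opposite directions (318 expected). FOSL1 and TAZ correlated at 0.00283, with a covariance of 0.00111 against a simulated 0.0533. They had 315 genes in the same direction (319 expected) and 717 in opposite directions (316 expected). Without EV replicate 1 the correlation with FOSL1 was 0.39 for YAP and 0.27 for TAZ, and without EV replicate 2 it was 0.37 and 0.24, where a single control library is shared. Among genes with a log2 CPM of at least 3 that of FOSL1 and TAZ was -0.27.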

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

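The tests on FOSL1 RNA levels were chosen after those levels were seen, and the slopes from single libraries after the slopes over all libraries were seen. Every result here was singled out because the effect of FOSL1 differed between lines by the interaction test, in 1312 genes for YAP and 452 genes for TAZ, with the numbers under each left-out library given in the results.

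For YAP with FOSL1, positive interactions were found for BCHE (1.63), SI (1.44), IGFBP5 (1.36), SLC16A7 (1.34), CBLN2 (1.30) and WWTR1 (0.81). Negative interactions were found for GBP3 (-3.70), MMP7 (-2.81), ANKRD1 (-2.64), RUNX1 (-2.60), THSD7A (-2.55), YAP1 (-0.62), CCN1 (-0.62) and TMPRSS2 (-0.39). YAP1 counts in the YAP lines include the transgene, so its value does not show how FOSL1 acts on the cell's own copy. SLC16A7 had an adjusted p of 0.074 without FOSL1 replicate 2, THSD7A of 0.072 without EV replicate 1 and 0.15 without YAP replicate 2, and CCN1 of 0.057 without EV replicate 1 and 0.058 without FOSL1 replicate 2. That of WWTR1 was 0.093 and 0.091 without EV replicates 1 and 2, 0.12 and 0.061 without FOSL1 replicates 1 and 2, 0.082 without YAP replicate 1 and 0.065 without YAP/FOSL1 replicate 2. The list medians were -0.46 for YAP/TAZ targets, -0.99 for basal markers, -0.26 for actin cytoskeleton and focal adhesion genes, 0.50 for cell cycle genes, -0.65 for interferon-stimulated genes and -0.63 for NF-kappaB genes.

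For TAZ with FOSL1, GUCY1A2 (2.23), AZGP1 (1.28), HPGD (1.25), TRPM8 (1.12), SNAI2 (1.09) and WWTR1 (0.72) were positive. WWTR1 counts in the TAZ lines include the transgene, so this value does not show how FOSL1 acts on the cell's own copy. MMP7 (-4.14), ADTRP (-2.27), NTN4 (-1.96), CAMK2N1 (-1.90), MYOF (-1.88), CCN1 (-0.83), TMPRSS2 (-0.38) and KLK3 (-0.37) were negative. The adjusted p of SNAI2 was 0.054 without EV replicate 1, 0.057 without FOSL1 replicate 2 and 0.058 without TAZ/FOSL1 replicate 1. That of NTN4 was 0.22 without EV replicate 1, 0.08 without EV replicate 2, 0.072 without FOSL1 replicate 1, 0.09 without FOSL1 replicate 2, 0.16 without TAZ replicate 1, 0.089 without TAZ/FOSL1 replicate 1 and 0.066 without TAZ/FOSL1 replicate 2. For CAMK2N1 it was 0.065 without EV replicate 1, 0.074 without FOSL1 replicate 1 and 0.064 without TAZ/FOSL1 replicate 1. That of WWTR1 was 0.14 without EV replicate 1, 0.16 without EV replicate 2, 0.26 without FOSL1 replicate 1, 0.089 without FOSL1 replicate 2, 0.059 without TAZ replicate 1 and 0.094 without TAZ/FOSL1 replicate 1. For KLK3 it was 0.1 without EV replicate 1, 0.076 without FOSL1 replicate 1, 0.066 without FOSL1 replicate 2, 0.08 without TAZ/FOSL1 replicate 1 and 0.07 without TAZ/FOSL1 replicate 2. That of TMPRSS2 was 0.06 without EV replicate 1, 0.06 without EV replicate 2, 0.07 without FOSL1 replicate 1, 0.057 without FOSL1 replicate 2 and 0.082 without TAZ/FOSL1 replicate 1. The list medians were -0.38 for YAP/TAZ targets, -0.95 for invasion genes linked to AP-1, 0.38 for cell cycle genes and -0.48 for NF-kappaB genes.

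Across genes the FOSL1 response was smaller in the YAP and TAZ lines, with slopes of 0.60 and 0.86. Noise between these libraries is argued against by the highest corrected slopes from single libraries, which were 0.65 and 0.89. Single-library slopes recombine the libraries that gave 0.60 and 0.86, so they are not an independent check. A lack of room in genes already moved by YAP or TAZ is argued against by highest slopes of 0.67 and 0.86 among genes with an unadjusted p above 0.5 in the single line. For the TAZ line a lower FOSL1 dose is argued against at the RNA level, since its FOSL1 RNA was 1.37 times that of the FOSL1 line. For the YAP line FOSL1 RNA was 0.466 times that of the FOSL1 line, so that a lower dose and an effect of YAP on the response cannot be told apart, because the level moves with the line. An effect of TAZ on the response to FOSL1 remains a hypothesis that may account for the TAZ line, found and tested on the same libraries. Differences between stable lines that arose by chance were not tested. Neither was a difference in vector between lines with and without YAP or TAZ, which the MIR30A counts given below leave open.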

How the results depend on the processing

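Settings are named where they took a number of genes beyond 1.5 times the reported one, moved a correlation beyond the spread between replicates, or ended or made a call, and the cause was not tested unless stated. No result of a named gene or a list changed direction across the threshold under the settings applied to it. The correlation of the FOSL1 and TAZ responses did change sign between settings, as given below. The numbers of genes stayed within 1.5 times under both other sets of size factors, DESeq2, the replicate block and the fit without mitochondrial genes, and these scalings moved the median of all genes by less than 0.1. Depth limits the genes named with few counts in EV, and 2 libraries per group limit what each leave-one-out fit can call.

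At an adjusted p under 0.01, by construction fewer, the number of genes was 824 in YAP against EV, 807 in TAZ against EV, 4042 in YAP/FOSL1 against EV, 2879 in YAP/FOSL1 against YAP and 2783 in YAP/FOSL1 against FOSL1. It was 1880 in TAZ/FOSL1 against FOSL1, 745 in YAP against TAZ, 1503 in YAP/FOSL1 against TAZ/FOSL1, 542 in the interaction of YAP with FOSL1 and 162 in the interaction of TAZ with FOSL1. The test against a fold of 1.5, which was added after the data were seen and by construction asks for larger changes, passed 1881 in FOSL1 against EV, 182 in YAP against EV, 125 in TAZ against EV, 919 in YAP/FOSL1 against EV and 1216 in TAZ/FOSL1 against EV. It passed 574 in YAP/FOSL1 against YAP, 388 in YAP/FOSL1 against FOSL1, 1327 in TAZ/FOSL1 against TAZ and 247 in TAZ/FOSL1 against FOSL1. It passed 166 in YAP against TAZ, 215 in YAP/FOSL1 against TAZ/FOSL1, 48 in the interaction of YAP with FOSL1 and 11 in the interaction of TAZ with FOSL1. With only the groups compared in the fit the number was 2354 in YAP/FOSL1 against YAP, 5983 in TAZ/FOSL1 against FOSL1, 546 in YAP against TAZ, 1830 in YAP/FOSL1 against TAZ/FOSL1 and 857 in the interaction of TAZ with FOSL1. The number fell in YAP/FOSL1 against YAP and in YAP against TAZ, between the lines with the noisiest replicates. It rose in TAZ/FOSL1 against FOSL1, between lines with quieter replicates. With no filter on low counts it was 2002 in the interaction of YAP with FOSL1.

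Leaving out 1 library at a time leaves a line with a lone library, which is assumed to vary like the other groups. The number of genes was then 644 to 1288 in YAP against EV, 669 to 1105 in TAZ against EV, 2429 to 5207 in YAP/FOSL1 against FOSL1 and 1649 to 1699 in TAZ/FOSL1 against FOSL1. It was 830 to 1064 in YAP against TAZ, 1253 to 3563 in YAP/FOSL1 against TAZ/FOSL1, 495 to 2978 in the interaction of YAP with FOSL1 and 127 to 313 in the interaction of TAZ with FOSL1. Among genes with a log2 CPM of at least 3 the correlation of responses was -0.27 for FOSL1 and TAZ, 0.07 for TAZ and YAP/FOSL1 and 0.08 for TAZ and TAZ/FOSL1. Without either EV library in turn it was 0.37 to 0.39 for FOSL1 and YAP, 0.24 to 0.27 for FOSL1 and TAZ, 0.64 to 0.66 for YAP and TAZ and 0.63 to 0.65 for YAP and YAP/FOSL1. It was 0.47 to 0.50 for YAP and TAZ/FOSL1, 0.44 to 0.47 for TAZ and YAP/FOSL1 and 0.46 to 0.49 for TAZ and TAZ/FOSL1, and here a single shared control adds covariance by construction.

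Replicate numbers did not pair the libraries of most lines, since of 15 correlations between same-numbered libraries' deviations, from -0.045 to 0.169, 1 exceeded 0.1. That was YAP with TAZ, at 0.169. Ribosomal protein genes took 6.07% and 5.34% of counts in YAP replicates 1 and 2, and 6.11% and 5.35% in TAZ. These 2 lines may thus share a replicate effect, which a block common to all lines does not model for them alone. With the replicate block in the model, 8000 genes changed in FOSL1 against EV and 1682 in YAP against EV. The block gave 1439 genes for the interaction of YAP with FOSL1 and 495 for that of TAZ.

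Of 260 list results, 48 were called with the preset correlation of 0.01 and not with an estimated one. The estimated correlation gave, for FOSL1 against EV, an adjusted p of 0.078 for other AP-1 members and 0.078 for stress response genes. For YAP against EV the adjusted p was 0.33 for Hippo factors, 0.11 for mesenchymal genes, 0.33 for actin genes, 0.33 for cholesterol genes and 0.33 for stress response genes. In TAZ against EV it gave 0.12 for other AP-1 members, 0.28 for invasion genes, 0.08 for cell cycle genes, 0.12 for cholesterol genes, 0.37 for stress response genes, 0.12 for hypoxia genes and 0.36 for fibroblast markers. For YAP/FOSL1 against EV the adjusted p was 0.29 for other AP-1 members, 0.14 for invasion genes and 0.27 for actin genes. In TAZ/FOSL1 against EV it gave 0.13 for invasion genes, 0.095 for mesenchymal genes and 0.18 for stress response genes. For YAP/FOSL1 against YAP the adjusted p was 0.22 for other AP-1 members, 0.069 for invasion genes and 0.23 for stress response genes. In YAP/FOSL1 against FOSL1 it gave 0.12 for other AP-1 members, 0.1 for invasion genes and 0.078 for stem cell markers. For TAZ/FOSL1 against TAZ the adjusted p was 0.16 for other AP-1 members and 0.083 for stress response genes. In TAZ/FOSL1 against FOSL1 it gave 0.081 for invasion genes, 0.17 for mesenchymal genes and 0.33 for stress response genes. For YAP against TAZ the adjusted p was 0.12 for other AP-1 members, 0.19 for mesenchymal genes, 0.19 for actin genes and 0.11 for cell cycle genes. In YAP/FOSL1 against TAZ/FOSL1 it gave 0.15 for mesenchymal genes and 0.22 for stress response genes. For the interaction of YAP with FOSL1 the adjusted p was 0.093 for other AP-1 members, 0.12 for stem cell markers and 0.11 for stress response genes. In the interaction of TAZ with FOSL1 it gave 0.18 for Hippo factors, 0.32 for other AP-1 members, 0.081 for basal markers, 0.094 for stem cell markers, 0.081 for actin genes, 0.081 for interferon genes, 0.081 for cholesterol genes and 0.11 for hypoxia genes.

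Adjusted p-values of lists whose call changed stand in brackets, where 0.05 is a rounded value on either side of the threshold. With size factors as in DESeq2 calls ended for actin genes (0.051) in YAP/FOSL1 against EV and mesenchymal genes (0.052) in YAP against TAZ. With upper-quartile factors calls ended for stress response genes (0.072) in TAZ against EV, mesenchymal genes (0.055) in YAP against TAZ and hypoxia genes (0.065) in the interaction of TAZ with FOSL1. Under that setting calls were made for hypoxia genes (0.032) in YAP/FOSL1 against YAP and fibroblast markers (0.042) in YAP/FOSL1 against FOSL1. With the replicate block calls ended for mesenchymal genes (0.05) in YAP against TAZ and stem cell markers (0.052) in the interaction of YAP with FOSL1. Under that setting calls were made for fibroblast markers (0.05) in YAP/FOSL1 against FOSL1. Without mitochondrial genes, a fit added after the data were seen, calls ended for mesenchymal genes (0.056) in YAP against TAZ. Under that setting calls were made for hypoxia genes (0.045) in YAP/FOSL1 against YAP. With no filter on low counts calls ended for Hippo factors (0.073) in YAP against EV, fibroblast markers (0.42) in TAZ against EV, stem cell markers (0.058) in YAP/FOSL1 against EV, other AP-1 members (0.054) in TAZ/FOSL1 against TAZ, mesenchymal genes (0.072) in TAZ/FOSL1 against FOSL1, stem cell markers (0.058) in the interaction of YAP with FOSL1 and stem cell markers (0.13) in the interaction of TAZ with FOSL1. Under that setting calls were made for actin genes (0.034) and immune cell markers (0.017) in TAZ/FOSL1 against EV, invasion genes (0.023), cholesterol genes (0.0099) and immune cell markers (0.011) in TAZ/FOSL1 against TAZ, stem cell markers (0.042) in TAZ/FOSL1 against FOSL1, hypoxia genes (0.022) and heat shock genes (0.044) in YAP against TAZ, mesenchymal genes (0.049) in the interaction of YAP with FOSL1.

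Leaving out 1 library changed list calls, with the lowest and highest adjusted p as follows. For YAP against EV they were 0.0065 to 0.078 for Hippo factors, 0.0065 to 0.23 for actin genes, 0.00094 to 0.39 for cholesterol genes and 0.00038 to 0.21 for stress response genes. In TAZ against EV the range was 0.008 to 0.2 for invasion genes, 0.0079 to 0.21 for stress response genes, 0.0079 to 0.1 for hypoxia genes and 0.0049 to 0.15 for fibroblast markers. For YAP/FOSL1 against EV they were 0.00075 to 0.062 for other AP-1 members, 0.0063 to 0.076 for invasion genes and 0.0035 to 0.083 for actin genes. In YAP/FOSL1 against YAP the range was 0.00017 to 0.055 for other AP-1 members, 0.019 to 0.39 for luminal markers and 0.015 to 0.17 for hypoxia genes. For YAP/FOSL1 against FOSL1 they were 0.012 to 0.1 for invasion genes, 0.045 to 0.14 for neuroendocrine markers and 0.00012 to 0.13 for fibroblast markers. In TAZ/FOSL1 against TAZ the range was 0.025 to 0.12 for cholesterol genes. For TAZ/FOSL1 against FOSL1 they were 0.02 to 0.071 for mesenchymal genes. In YAP against TAZ the range was 0.037 to 0.5 for Hippo factors, 0.037 to 0.12 for basal markers, 0.01 to 0.14 for mesenchymal genes, 0.0021 to 0.082 for actin genes and 0.026 to 0.4 for hypoxia genes. For YAP against TAZ they were 0.046 to 0.53 for fibroblast markers and 0.024 to 0.53 for heat shock genes. In YAP/FOSL1 against TAZ/FOSL1 the range was 0.039 to 0.93 for other AP-1 members and 0.01 to 0.94 for fibroblast markers. For the interaction of YAP with FOSL1 they were 0.04 to 0.29 for invasion genes, 0.024 to 0.11 for stem cell markers, 0.049 to 0.35 for mesenchymal genes and 4e-04 to 0.29 for fibroblast markers. In the interaction of TAZ with FOSL1 the range was 0.0046 to 0.19 for Hippo factors, 0.012 to 0.16 for other AP-1 members, 0.016 to 0.079 for basal markers, 0.016 to 0.076 for stem cell markers and 0.0099 to 0.081 for interferon genes. For the interaction of TAZ with FOSL1 they were 0.025 to 0.18 for hypoxia genes.

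Of the transgenes, FOSL1 kept every call, but the size of its change against EV moved when 1 library was left out. Its log2 fold change ranged from 10.96 to 12.34 in FOSL1, 9.86 to 11.24 in YAP/FOSL1 and 11.42 to 12.80 in TAZ/FOSL1. It ranged from 10.75 to 12.65 in YAP/FOSL1 against YAP. WWTR1 in YAP against EV was -0.32 with no filter on low counts and passed (adjusted p = 0.028). YAP1 in YAP/FOSL1 against YAP was -0.19 with upper-quartile factors and no longer passed (adjusted p = 0.056). WWTR1 in YAP/FOSL1 against YAP was -0.34 with no filter on low counts and passed (adjusted p = 0.025). WWTR1 in YAP/FOSL1 against FOSL1 was 0.46 with RLE size factors and no longer passed (adjusted p = 0.051). Leaving out 1 library, with calls that changed, gave log2 fold changes of -0.30 to -0.14 for YAP1 in YAP/FOSL1 against YAP, -0.60 to -0.13 for WWTR1 in YAP/FOSL1 against YAP and 0.21 to 0.69 for WWTR1 in YAP/FOSL1 against FOSL1. It gave 0.14 to 0.30 for YAP1 in TAZ/FOSL1 against TAZ, 0.55 to 1.02 for WWTR1 in the interaction of YAP with FOSL1 and 0.65 to 0.82 for WWTR1 in the interaction of TAZ with FOSL1. Of 1292 results of named genes, 4 calls ended and 3 were made with size factors as in DESeq2, 15 and 10 with upper-quartile factors, and 4 and 38 with no filter. The numbers were 2 and 7 with the replicate block and 5 and 3 without mitochondrial genes, while DESeq2 ended 36 and made 9 of 1196. Leaving out 1 library ended 553 and made 45 calls in 5944 tests.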

Other observations

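Further genes of the fixed lists moved in the single lines. In YAP against EV, HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.49 ± 0.06 (adjusted p = 8.3e-06) and the disulfide isomerase gene PDIA6 by 0.42 ± 0.06. PEG10, a retrotransposon-derived gene of the neuroendocrine list, changed by -1.29 ± 0.12 (adjusted p = 2.4e-07) in YAP and 0.71 ± 0.10 (adjusted p = 6.9e-06) in FOSL1. EGFR, the epidermal growth factor receptor gene, rose by 0.52 ± 0.08 in YAP, and HMGCS1, of cholesterol synthesis, by 0.60 ± 0.06. In TAZ against EV, P4HA1, a collagen prolyl hydroxylase gene, rose by 0.49 ± 0.07 and the hexokinase gene HK2 by 0.39 ± 0.06, while HK2 changed by -0.70 ± 0.06 and the kinase gene PDK1 by -0.91 ± 0.07 in FOSL1.

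The tests of the shared EV libraries, of single libraries and on MIR30A were chosen after their results or those of all libraries were seen. Genes changed in both FOSL1 and TAZ against EV went in opposite directions in 717 cases and in the same direction in 315. Among genes with a log2 CPM of at least 3, a trend on gene length and expression level is argued against as the whole cause. The correlation across these 10117 genes was -0.28 before and after removal of the trend. From single libraries, with another EV library for each response, it was -0.32 to -0.25. The shared EV libraries would push the responses together, yet the covariance was below that of simulated unchanged groups (difference -0.0522). The simulations used the spread over all lines. The chi-square per degree of freedom between replicates was 2.47 in EV against 6.93 in TAZ, 8.91 in YAP and 10.8 in YAP/FOSL1. The simulated covariance may thus be too high, and part of the difference may come from that. The correlation depended on the genes taken and on the EV libraries, at 0.00283 over all genes, 0.27 without EV replicate 1 and 0.24 without EV replicate 2, where a single control raises it by construction. Opposed effects of FOSL1 and TAZ on part of the genes may account for the pattern, as a hypothesis.

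MIR30A, singled out after its values were seen, was counted 848 and 705 times in EV and 458 and 539 times in FOSL1, and 0 times in the other 8 libraries (hg19 chromosome 6, 72113254 to 72113324). Of genes with at least 50 counts in every EV and FOSL1 library, it was the 1 gene at 0 in all others, and 0 genes had the opposite pattern. Loss or silencing of the region around it is argued against by its 10 tested neighbours within 1 Mb. Their median log2 fold changes were -0.02 in YAP and -0.06 in TAZ against EV, and the lowest were -0.74 and -0.83. These neighbours do not address a loss confined to MIR30A. In EV its counts were 16.9 times those of its whole host gene LINC00472 (1553 against 92), as a microRNA-30 backbone in the vector of the EV and FOSL1 lines would give. YAP/FOSL1 and TAZ/FOSL1 expressed FOSL1 and had 0 MIR30A counts, so a backbone in the FOSL1 vector itself would need another FOSL1 vector there. A backbone in an empty vector that the FOSL1 line also carried would not need one, and whether it did is not known. The labels do not name the vectors, and the explanation stays open until reads or vector maps are seen. A difference in vector between lines with and without YAP or TAZ could not be separated from the transgene by these fold changes.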
